A study of Mus musculus with 11 samples.

How the data were processed

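RNA was measured in the gastrocnemius muscle of 11 mice by 3' tag sequencing (QuantSeq 3' mRNA FWD, in which reads come from near the 3' end of polyadenylated transcripts), from 450 ng of total RNA per library according to the labels. The mice fell into 3 groups by genotype. The 4 wild-type mice, the 3 mice with an inducible Raptor knockout and the 4 mice with an inducible knockout of both Raptor and mTOR were each 1 library and 1 replicate, numbered here in the order of the sample records. Raptor (gene symbol Rptor) is the defining subunit of mTOR complex 1, and mTOR (Mtor) is the kinase that this complex shares with mTOR complex 2. The Cre recombinase was fused to a mutated oestrogen receptor domain and driven by the human skeletal actin promoter, which is active in myofibres. Per the labels, tamoxifen was given to 3-month-old mice, in chow for 7 weeks, and muscles were collected 7 months after it was begun.

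The deposited gene tables hold expected counts per gene, which the authors made with fastp 0.20.0, STAR 2.7.0 and RSEM 1.3.3 on GRCm38, also named mm10, and did not normalize. A deposited table of all 11 libraries holds TPM, transcripts-per-million, per library. The annotation release, any filters and the strand setting were not given in the sources used here, and GENCODE M21 was the annotation used for positions and transcript lengths. The counts came from 2 sequencing runs: 2 double-knockout libraries (replicates 3 and 4) were in the smaller run, and the other 9 libraries were in the larger run. A further 6 columns of the deposited tables matched no sample label and were not used.

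Expected counts were rounded to whole numbers. Of all values, 2.25% were not whole, and rounding moved a library total by at most 30.2 counts. Library totals ran from 2791339 to 6328533 counts over 55487 genes, a ratio of 2.27. No pair of libraries was a repeat of the same library: the lowest chi-square per degree of freedom between libraries was 3.22.

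Genes were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM normalization, a robust quasi-likelihood fit of the 3 groups with all 11 libraries and no covariate, and the quasi-likelihood F test, two-sided, for each of 3 contrasts. The filter left 10505 genes, which held 99.54% of the counts, and 8 of them had no gene symbol. The p-values were adjusted by the Benjamini-Hochberg method within each contrast and called at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Levels are given as counts-per-million scaled by TMM (CPM), as the mean and SD over the libraries of a group. The common dispersion gave a biological coefficient of variation of 20.6%, and the fit had 8 residual degrees of freedom.

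Of 41 gene lists, 40 had at least 5 tested members and were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the 40 lists within a contrast. The lists were tested again with an estimated correlation and with fry, which asks whether the members move in 1 direction without comparing them with other genes. Members were counted by the adjusted p over all tested genes and by a p adjusted over the list alone. The gene lists, the tests and the rule for naming genes were chosen before the data were examined. The rule named Rptor and Mtor in each contrast, then the 8 largest rises and the 8 largest falls. These had an adjusted p under 0.05, a mean log2 CPM of at least 3, groups that did not overlap, and a symbol other than a predicted gene or pseudogene. From each list described it named up to 4 members with the smallest adjusted p, or 2 with the highest mean CPM where none passed. Genes named outside the rule are pointed out where they occur.

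The alternatives were: DESeq2 size factors or library totals in place of TMM; no filter on low counts; only the 2 groups compared in the fit; sequencing run as a covariate; the 2 libraries of the smaller run left out; the DESeq2 1.42.0 Wald test; limma on log2 of the deposited TPM with a pseudocount of 1 or 0.1, over 10342 genes with a mean TPM of at least 1; and each library left out in turn. Alternatives with a covariate for Xist, with the libraries lacking Xist alone, and with a covariate for mt-Rnr2 (log2 of its counts per library total) were chosen after seeing the data. Both comparisons with wild type use the same 4 libraries. Their overlap was therefore set beside 20 simulations in which all 3 groups were drawn from the wild-type means and both comparisons used the same wild-type draws, and beside the 6 ways to give 2 wild-type libraries to each comparison. The pipeline was tested on simulated data with 200 changed genes per contrast. It recovered 92.1% (double knockout against wild type), 96.9% (double knockout against Raptor knockout) and 93.8% (Raptor knockout against wild type) of tested 4-fold changes. Of 2-fold changes it recovered 44.8%, 39.4% and 49.3%, and of 1.5-fold changes 10.6%, 6.25% and 1.52%. The calls of those runs held 6 false calls of 101, 12 of 104 and 1 of 96. Between the knockouts the simulated data gave 104 calls and the real data 3, so the adjusted threshold was stricter in the real data. Recovery there may be lower than these shares.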

Results

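The data were gene counts from the gastrocnemius, a mixed hindlimb muscle, of 4 wild-type mice, 3 mice with an inducible muscle Raptor knockout and 4 mice with a knockout of both Raptor and mTOR. Library totals ran from 3134575 to 6328533 counts in wild type, from 3223797 to 3764879 in the Raptor knockout and from 2791339 to 3536731 in the double knockout. Between 15032 and 16726 genes had a count in each library, and 10505 were tested. All levels are TMM-scaled CPM as mean ± SD with n = 4 wild-type, n = 3 Raptor-knockout and n = 4 double-knockout libraries, and each log2 fold change stands with its SE. On the first principal component, with 39.5% of the variance, the wild-type libraries lay between -49.8 and -33.4 and the knockout libraries of both kinds between 11.8 and 37.9. Xist, the transcript of the inactive X chromosome, stood at 95.6 to 208 CPM in wild-type replicate 3 and double-knockout replicates 1 to 3. The Y-linked Ddx3y stood at 59.6 to 91.8 CPM in the other 7 libraries, among them every Raptor-knockout library. The labels give no sex.

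Rptor (ENSMUSG00000025583, GRCm38 chromosome 11, 119602905 to 119899576), which encodes the mTOR complex 1 subunit Raptor, stood at 9.83 ± 0.946 CPM in wild type. It stood at 4.57 ± 0.630 in the Raptor knockout and 4.83 ± 0.566 in the double knockout. It fell by 1.11 on the log2 scale in the Raptor knockout (SE 0.23, edgeR adjusted p = 0.00282) and by 1.02 in the double knockout (SE 0.21, edgeR adjusted p = 0.00156), with every knockout library below every wild-type library. Between the knockouts its log2 fold change was 0.08 ± 0.24 (edgeR adjusted p = 0.955). Mtor (ENSMUSG00000028991, chromosome 4, 148448611 to 148557683), which encodes the kinase itself, stood at 20.8 ± 5.95 CPM in wild type, 20.6 ± 2.24 in the Raptor knockout and 35.9 ± 3.36 in the double knockout. Its gene counts rose in the double knockout against wild type (log2 fold change 0.78 ± 0.18, edgeR adjusted p = 0.00534) and were 0.80 ± 0.20 against the Raptor knockout (edgeR adjusted p = 0.162). Its log2 fold change was -0.02 ± 0.20 for the Raptor knockout against wild type (edgeR adjusted p = 0.962). The positions of the loxP sites were not given in the sources used here, so tags from the 3' end do not show whether the floxed part of either gene was lost. The gene counts alone also do not show which Mtor transcript the tags came from, so their rise does not show more of the full-length transcript. On the deposited TPM, tested with limma, the Rptor calls ended. With a pseudocount of 1 its log2 fold changes against wild type were -0.50 in the Raptor knockout and -0.31 in the double knockout. With 0.1 they were -0.85 and -0.50, and its TPM was 0.69 to 1.81. Mtor on TPM was higher in the double knockout, by 3.03 against wild type and 3.09 against the Raptor knockout (pseudocount 1). Its TPM per unscaled CPM was 2.46 higher there than in the other libraries on the log2 scale. These TPM values therefore do not show abundance alone. In the libraries without Xist the double-knockout calls of Rptor (-1.25) and Mtor (0.87) against wild type ended. The Mtor difference between the knockouts was also called by the DESeq2 Wald test, with no filter and with only the 2 groups in the fit (0.81 in each).

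**Figure D1:**
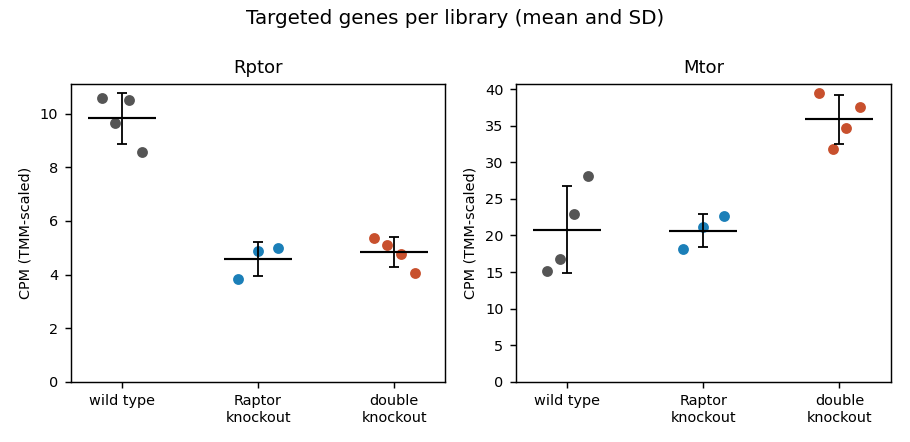
CPM (TMM-scaled, linear axis from 0) of Rptor and Mtor in each library of the 3 genotypes, with 1 point per library, a line at the mean and a bar of 1 SD. The Rptor means were 9.83, 4.57 and 4.83 and the Mtor means 20.8, 20.6 and 35.9 in wild type, Raptor knockout and double knockout.

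The comparison of the double knockout with wild type, a contrast the study names, asks how muscle RNA differs when both genes are targeted. In double-knockout muscle, camera called the lists of developing fibres, the neuromuscular junction, slow-fibre sarcomeres, ribosomal proteins and extracellular matrix higher. It called fast-fibre sarcomeres, calcium handling, glycolysis and glycogen, and amino acid, creatine and polyamine metabolism lower, with 8 of 13, 18 of 43, 11 of 31 and 18 of 28 members lower. With an estimated correlation the developmental and junction lists kept their calls (adjusted p = 0.0201 and 0.0254) and the other lists named here did not (adjusted p from 0.142 to 0.515). The stress-responsive titin-binding protein Ankrd1 rose 35.3-fold, from 38.1 ± 14.8 to 1346 ± 102 CPM. The S-adenosylmethionine decarboxylase gene Amd1, a step of polyamine synthesis, fell 17.97-fold, from 1865 ± 1009 to 104 ± 7.28 CPM. In wild-type replicate 3, the only wild-type library with Xist, Amd1 stood at 420 CPM, against 2034 to 2756 in the other wild-type libraries. Reads of Amd1 and its near-identical copy Amd2 (20.9-fold lower) cannot be assigned with certainty.

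In all, 1367 genes rose and 1435 fell, 595 and 555 of them by more than 2-fold. At an unadjusted p under 0.05 there were 3985 genes. All 4 double-knockout libraries lay on 1 side of all 4 wild-type libraries for 2321 of the called genes, and for 26.8% of all tested genes, where chance gives 2.86%. The smallest called change was 1.24-fold. With library totals in place of TMM the split became 2421 higher and 844 lower, as the median of all genes moved by 0.23 on the log2 scale, and on TPM it was 1766 and 779 with a shift of 0.15, with Myh3 at 2.75 against 4.03 and Myh8 at 3.10 against 4.64. In the libraries without Xist, with 1 double-knockout library assumed to vary like the others, 238 rose and 234 fell. Many of the genes named for this comparison lost their calls there. Among them were Irs2 (log2 fold change 0.67), Tsc1 (-0.87), Tfeb (-0.93), mt-Nd2 (-0.64), Myh7 (0.70) and Cryab (0.85). Tnni1 (2.30-fold against 4.57-fold), Xirp1 (4.11-fold against 6.50-fold) and Atf3 (3.90-fold against 8.46-fold) kept theirs with smaller changes. With an Xist covariate Amd1 was -3.26 against -4.17, Amd2 -3.57 against -4.38 and Atf3 2.37 against 3.08, and without the smaller run Atf3 was 3.67. Within the larger sequencing run, which leaves 2 double-knockout libraries, 945 rose and 974 fell.

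Genes of developing and regenerating fibres had the highest median of the 40 lists. Of 16 tested members, 11 rose and 1 fell (11 and 1 adjusted over the list alone), with a median log2 fold change of 1.59. Embryonic myosin heavy chain Myh3 rose 16.4-fold, from 3.37 ± 1.11 to 56.8 ± 11.6 CPM, and neonatal Myh8 rose 24.9-fold, from 2.66 ± 1.52 to 69.4 ± 20.05. The growth factor Igf2 rose 12.8-fold, and Myod1, a myogenic transcription factor, rose 3.16-fold. The list passed camera (adjusted p = 1.67e-08) and kept its call with an estimated correlation (adjusted p = 0.0201). The list of the neuromuscular junction and the denervation response had 15 of 23 members higher and 0 lower (16 and 1 adjusted over the list alone), with a median of 0.93. Myogenin (Myog), a transcription factor of muscle differentiation that is also in the developmental list, rose 22.02-fold. The acetylcholine receptor subunits Chrna1 and Chrnb1 rose 4.88-fold and 2.71-fold. Its camera call (adjusted p = 1.6e-06) also held with an estimated correlation (adjusted p = 0.0254). Sarcolipin (Sln), a small inhibitor of the sarcoplasmic reticulum calcium pump, rose 17.2-fold, from 14.9 ± 12.4 to 255 ± 67.2 CPM (log2 fold change 4.11, and 4.91 without wild-type replicate 1).

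Slow and fast sarcomere genes went opposite ways. Of 12 slow-fibre genes, 9 rose and 1 fell (the same counts adjusted over the list alone), with a median of 1.33. Slow troponin I (Tnni1) rose from 30.3 ± 7.48 to 138 ± 40.8 CPM and the slow myosin heavy chain Myh7 from 93.3 ± 25.3 to 264 ± 63.2. Of 13 fast-fibre genes, 8 fell and 2 rose (8 and 2 adjusted over the list alone), with a median of -0.44. Fast troponin I (Tnni2) fell from 14569.8 ± 1453 to 6712 ± 241 CPM, fast troponin T (Tnnt3) from 9818 ± 457 to 4577 ± 583 and tropomyosin Tpm1 from 19938 ± 733 to 7985 ± 446. Camera called both lists (adjusted p = 5.4e-05 for slow and 0.00919 for fast). Neither call held with an estimated correlation (adjusted p = 0.273 and 0.32), and the fast list was not called in the libraries without Xist. Of 31 sarcomere genes shared by fibre types, 15 rose and 3 fell (16 and 4 adjusted over the list alone; camera adjusted p = 0.0225, and adjusted p = 0.273 with an estimated correlation). Its call ended without the smaller run. Xirp1, an actin-binding protein of the fibre ends and of damage sites, rose 6.50-fold, and the Z-disc protein Tcap fell 3.73-fold.

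Among 43 genes of excitation-contraction coupling and calcium handling, which carry the signal from the membrane to contraction and back to rest, 18 fell and 6 rose (20 and 8 adjusted over the list alone), with a median of -0.41. Parvalbumin (Pvalb), a calcium buffer of fast fibres, fell 3.21-fold, from 8073 ± 841 to 2518 ± 424 CPM. Myoregulin (Mrln), an inhibitor of the sarcoplasmic reticulum calcium pump, fell 3.26-fold. The list passed camera (adjusted p = 0.0111) but not with an estimated correlation (adjusted p = 0.273), nor with an Xist covariate. The kinase gene Mylk4 fell 7.51-fold and Mss51, a muscle protein tied to mitochondrial metabolism, fell 19.98-fold.

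Ribosomal protein genes rose nearly as a whole. Of 78 tested, 74 rose and 0 fell (75 and 0 adjusted over the list alone), with a median of 0.93. Rpl23 rose from 681 ± 83.7 to 1829 ± 78.6 CPM and Rps28 from 368 ± 40.8 to 860.0 ± 55.96. Camera gave an adjusted p = 4.72e-33, and the estimated correlation an adjusted p = 0.166. Of 33 translation factors and ribosome biogenesis genes, 13 rose and 1 fell (13 and 2 adjusted over the list alone; camera adjusted p = 0.00482, and adjusted p = 0.142 with an estimated correlation). The elongation factor Eef1a1 rose 4.73-fold and Eef2 rose 1.99-fold. Cytosolic heat shock proteins had 10 of 22 members higher and 0 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.00924, and adjusted p = 0.273 with an estimated correlation). The small heat shock protein Cryab rose from 1053 ± 329 to 2422 ± 373 CPM. In the libraries without Xist the heat shock call ended.

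Camera called the lists of amino acid, glycogen, fatty acid and mitochondrially encoded genes lower, with an adjusted p from 0.142 to 0.515 with an estimated correlation. It did not call sterol and fatty acid synthesis (median 0.26, camera adjusted p = 0.699), the tricarboxylic acid cycle (-0.25, camera adjusted p = 0.0791) or mitochondrial biogenesis regulators (-0.27, camera adjusted p = 0.0565). In the list of amino acid, creatine and polyamine metabolism 18 of 28 genes fell and 2 rose (18 and 2 adjusted over the list alone), with a median of -0.86. Oxct1, which activates ketone bodies for oxidation, fell 7.83-fold, from 404 ± 112 to 51.6 ± 5.89 CPM. The alanine aminotransferase Gpt2 fell 4.79-fold, and the spermine oxidase Smox fell 7.41-fold. Camera called the list (adjusted p = 3.4e-07), and the call was lost with an estimated correlation (adjusted p = 0.142). Of 31 glycolysis and glycogen genes, 11 fell and 5 rose (12 and 5 adjusted over the list alone; camera adjusted p = 0.0291, and adjusted p = 0.515 with an estimated correlation). The phosphorylase kinase subunits Phka1 and Phkg1, which switch on glycogen breakdown, fell 3.80-fold and 2.97-fold. The glycolysis call ended with library totals, with an Xist covariate, in the libraries without Xist and without wild-type replicate 4 or double-knockout replicate 1 or 3. Of 27 fatty acid genes, 10 fell and 1 rose (13 and 1 adjusted over the list alone; camera adjusted p = 0.00924, and adjusted p = 0.273 with an estimated correlation), among them Fabp3, a fatty acid carrier of muscle (2.83-fold). Of 13 mitochondrially encoded genes, 6 fell and 0 rose (6 and 0 adjusted over the list alone; camera adjusted p = 0.0225, and adjusted p = 0.434 with an estimated correlation). The complex I gene mt-Nd2 fell 1.92-fold. This list lost its call with an Xist covariate, in the libraries without Xist and without double-knockout replicate 1.

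Extracellular matrix genes were higher in 30 of 40 cases and lower in 0 (34 and 0 adjusted over the list alone), with a median of 0.97. Thrombospondin 4 (Thbs4) rose from 52.3 ± 2.30 to 178 ± 33.5 CPM and fibronectin (Fn1) from 17.5 ± 4.30 to 61.1 ± 17.6. Camera called the list (adjusted p = 2.22e-12), and the estimated correlation gave an adjusted p = 0.261. Markers of other cells moved with it, but some of these lists share members with the matrix list. The fibro-adipogenic list shares Col1a1, Col3a1, Dcn, Lum and Fbn1 with it, and the tenocyte list Thbs4, Fmod and Col1a1. Macrophage and monocyte markers had 10 of 16 higher and 0 lower (12 and 0 adjusted over the list alone; median 0.98, camera adjusted p = 3.49e-05, and adjusted p = 0.273 with an estimated correlation), such as galectin 3 (Lgals3, 3.18-fold). Fibro-adipogenic and fibroblast markers had 10 of 19 higher and 1 lower (11 and 1 adjusted over the list alone; median 0.60, camera adjusted p = 0.000106, and adjusted p = 0.287 with an estimated correlation). Tenocyte markers had 4 of 9 higher (4 adjusted over the list alone; median 0.81, camera adjusted p = 0.0169, and adjusted p = 0.273 with an estimated correlation), a call that ended in the libraries without Xist. Endothelial markers had 2 of 17 higher, with a median of 0.11 (camera adjusted p = 0.665).

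Immediate early genes, transcription factors and regulators that respond within minutes to stimulation, had 9 of 20 members higher and 0 lower (13 and 0 adjusted over the list alone), with a median of 1.13. Atf3 rose from 5.25 ± 2.66 to 47.3 ± 28.1 CPM and Junb from 5.88 ± 3.23 to 28.6 ± 5.92. Camera called the list (adjusted p = 2.82e-06), and the estimated correlation gave an adjusted p = 0.273. Wild-type replicate 3, which carries Xist, had a list mean of 4.70 log2 CPM against 3.28 to 3.52 in the other wild-type libraries. Some lists of interest were not called. Of 31 mTOR pathway genes, 5 rose and 9 fell (the same counts adjusted over the list alone; camera adjusted p = 0.185), with Irs2, an insulin receptor adaptor, 2.06-fold higher and Tsc1, an inhibitor of the pathway, 1.88-fold lower. Ubiquitin ligases and atrophy genes had 3 higher and 8 lower of 26 (3 and 10 adjusted over the list alone; camera adjusted p = 0.266), and the sign of their median (-0.15) turned with library totals and on TPM, which moved the median of all genes by 0.23 and 0.15. Of 57 autophagy and lysosome genes, 9 rose and 15 fell (10 and 17 adjusted over the list alone; camera adjusted p = 0.649). Tfeb, a transcription factor of lysosomal genes, fell 2.14-fold and the autophagy kinase Ulk2 2.26-fold. The autophagy median was 0.09 and its mean -0.01.

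**Figure D2:**
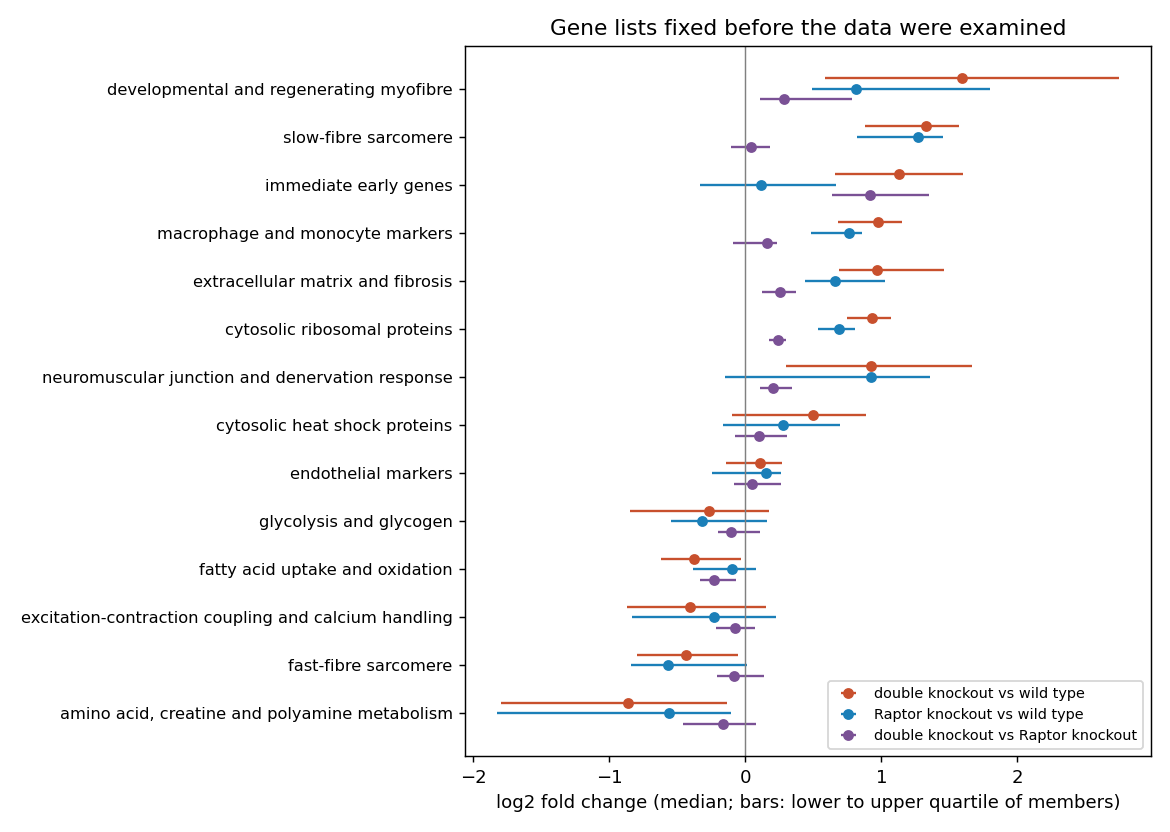
Median log2 fold change (horizontal axis, points) of 14 gene lists (vertical axis) in the 3 comparisons, with bars from the lower to the upper quartile of the members. In the double knockout against wild type the developmental fibre median was 1.59, the ribosomal protein median 0.93, the endothelial median 0.11 and the median of amino acid, creatine and polyamine metabolism -0.86.

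**Figure D3:**
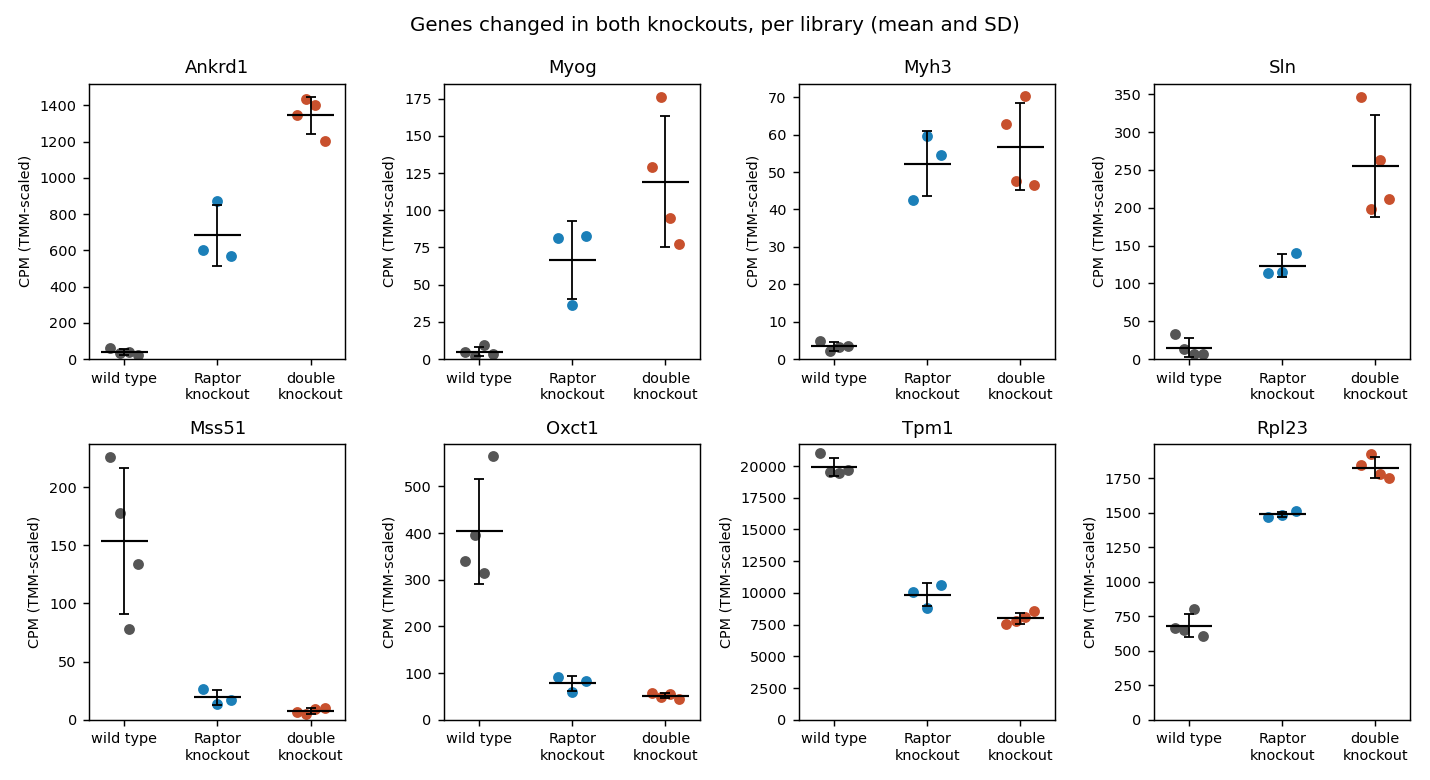
CPM (TMM-scaled, linear axes from 0) of Ankrd1, Myog, Myh3, Sln, Mss51, Oxct1, Tpm1 and Rpl23 in each library of the 3 genotypes, with 1 point per library, a line at the mean and a bar of 1 SD. Ankrd1 averaged 38.1, 682 and 1346 CPM in wild type, Raptor knockout and double knockout, and Tpm1 averaged 19938, 9851 and 7985.

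The Raptor knockout against wild type is the step that the contrasts named by the study leave implied. In Raptor-knockout muscle, camera called the lists of developing fibres, the neuromuscular junction, slow-fibre sarcomeres, ribosomal proteins and extracellular matrix higher, and fast-fibre sarcomeres and amino acid, creatine and polyamine metabolism lower. With an estimated correlation the developmental list kept its call (adjusted p = 0.0354) and the other lists named here did not (adjusted p from 0.081 to 0.362). Ankrd1 rose 17.9-fold, to 682 ± 167 CPM, and Myh3 rose 15.1-fold, to 52.2 ± 8.74. The chemokine Cx3cl1 rose 16.7-fold, from 2.10 ± 0.840 to 35.7 ± 13.6 CPM. Amd1 fell 11-fold, to 169.5 ± 40.8 CPM, and Gpt2 fell 6.99-fold, to 16.2 ± 0.462. The 7SL RNA copies Rn7s1 and Rn7s2, whose reads cannot be told apart, each fell 8.23-fold (log2 fold change -3.04), with -3.83 without Raptor-knockout replicate 2 and -2.18 with an mt-Rnr2 covariate. Within each group the libraries had the same order by Rn7s1 as by mt-Rnr2. In wild type, replicate 4 had 12.6 CPM of Rn7s1 against 39.5 to 53.8 in the others. Part of this fall therefore cannot be told apart from the spread of mt-Rnr2.

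All libraries of both groups were in the larger sequencing run. In this comparison 917 genes rose and 991 fell, 423 and 410 of them by more than 2-fold, and 3333 had an unadjusted p under 0.05. The groups did not overlap for 1768 of the called genes and for 27.3% of all tested genes, where chance gives 5.71%. With library totals the split became 1638 higher and 573 lower, as the median of all genes moved by 0.20, and on TPM it was 1031 and 519 with a shift of 0.10, with log2 fold changes of 2.61 for Myh3 against 3.91, 1.90 for Myh8 against 3.36, 2.78 for Cx3cl1 against 4.06 and -1.07 for Itpr1 against -2.00. Without Raptor-knockout replicate 1 the counts were 556 and 584, without replicate 3 they were 597 and 627, and in the libraries without Xist they were 555 and 710.

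Of 16 developmental genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.81. Myh8 rose 10.2-fold and the intermediate filament gene Nes, expressed in immature fibres, 2.65-fold. Camera called the list (adjusted p = 3.54e-07), and the call held with an estimated correlation (adjusted p = 0.0354). Junction and denervation genes had 13 higher and 1 lower of 23 (14 and 1 adjusted over the list alone; median 0.92, camera adjusted p = 0.000131, and adjusted p = 0.081 with an estimated correlation). Chrna1 rose from 12.5 ± 3.28 to 50.3 ± 7.16 CPM and Myog from 5.03 ± 3.20 to 66.9 ± 26.3. Slow-fibre genes had 9 higher and 1 lower of 12 (10 and 1 adjusted over the list alone; median 1.27, camera adjusted p = 6.62e-06, and adjusted p = 0.306 with an estimated correlation). Fast-fibre genes had 2 higher and 8 lower of 13 (2 and 8 adjusted over the list alone; median -0.57, camera adjusted p = 0.0062, and adjusted p = 0.362 with an estimated correlation). Tnni1 rose 4.47-fold and Tnni2 fell 1.85-fold. Excitation-contraction coupling genes had 7 higher and 12 lower of 43 (9 and 14 adjusted over the list alone). The list was not called (camera adjusted p = 0.117) but passed with no filter, with an mt-Rnr2 covariate, in the libraries without Xist and without wild-type replicate 3. Itpr1, an intracellular calcium channel, fell 3.99-fold.

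Ribosomal protein genes had 66 of 78 higher and 0 lower (73 and 0 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 1.87e-26, and adjusted p = 0.166 with an estimated correlation). Rps20 rose from 469 ± 97.2 to 1096 ± 0.394 CPM. Extracellular matrix genes had 17 of 40 higher and 0 lower (22 and 1 adjusted over the list alone; median 0.66, camera adjusted p = 3.86e-09, and adjusted p = 0.302 with an estimated correlation), with Fn1 3.35-fold higher. Beside them, macrophage and monocyte markers had 6 of 16 higher and 0 lower (6 and 0 adjusted over the list alone; median 0.76, camera adjusted p = 0.00558, and adjusted p = 0.407 with an estimated correlation). Fibro-adipogenic and fibroblast markers had 5 of 19 higher and 1 lower (8 and 1 adjusted over the list alone; median 0.41, camera adjusted p = 0.00558, and adjusted p = 0.488 with an estimated correlation). Tenocyte markers had 4 of 9 higher (4 adjusted over the list alone; median 0.69, camera adjusted p = 0.00471, and adjusted p = 0.166 with an estimated correlation). Endothelial markers had 1 of 17 higher, with a median of 0.15 (camera adjusted p = 0.795). Amino acid, creatine and polyamine genes had 14 of 28 lower and 1 higher (the same counts adjusted over the list alone; median -0.56, camera adjusted p = 6.62e-06, and adjusted p = 0.166 with an estimated correlation), with ornithine decarboxylase (Odc1), the first step of polyamine synthesis, 2.52-fold lower.

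Of 31 mTOR pathway genes, 2 rose and 11 fell (3 and 13 adjusted over the list alone; median -0.33, camera adjusted p = 0.0134, and adjusted p = 0.166 with an estimated correlation). The kinase Sgk1, a target of mTOR complex 2 signalling, fell from 67.3 ± 6.39 to 22.3 ± 8.18 CPM, and Rps6 rose 1.66-fold. Ubiquitin ligases and atrophy genes had 0 higher and 9 lower of 26 (0 and 9 adjusted over the list alone; median -0.31, camera adjusted p = 0.0325, and adjusted p = 0.412 with an estimated correlation). Asb2, a substrate receptor of a ubiquitin ligase, fell 2.71-fold, and Klf15, a transcription factor induced by glucocorticoids, fell 3.46-fold. Genes of the integrated stress response and ATF4 had 5 of 25 lower and 0 higher (7 and 0 adjusted over the list alone; median -0.30, camera adjusted p = 0.0325, and adjusted p = 0.166 with an estimated correlation). Herpud1, a factor of protein degradation at the endoplasmic reticulum, fell 1.55-fold. Both of these camera calls ended with an Xist covariate, in the libraries without Xist and without wild-type replicate 3 or Raptor-knockout replicate 2. The stress response call also ended with no filter, without the smaller run and without wild-type replicate 4 or Raptor-knockout replicate 1, and the ligase call with only the 2 groups in the fit.

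Both comparisons with wild type used the same 4 wild-type libraries. Of the called genes, 771 rose in both, 836 fell in both and 2 went opposite ways. Drawing the calls independently would share 119.3 and 135.4. Across all tested genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.767, against 0.455 on average in simulations of unchanged groups that share their wild-type libraries. The covariance was 0.411, against 0.0641 in the simulations. With separate wild-type libraries for each comparison, 393 to 473 genes were shared higher and 501 to 543 lower, 0 to 35 went opposite ways, and r was 0.443 to 0.676. Ankrd1, Myh3, Myog, Amd1 and Mss51 were among the largest changes in both knockouts.

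**Figure D4:**
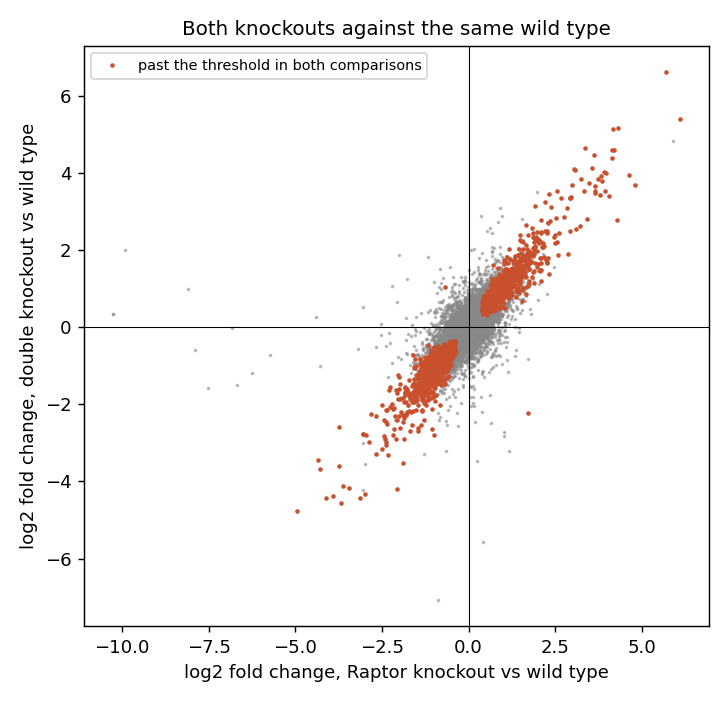
Log2 fold change of each tested gene in the double knockout (vertical axis) against that in the Raptor knockout (horizontal axis), each relative to wild type, with genes past the threshold in both marked. The 771 genes higher in both lie at the upper right and the 836 lower in both at the lower left.

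The double knockout against the Raptor knockout, the other contrast the study names, asks what targeting mTOR adds. Xist was counted in 3 of 4 double-knockout and 0 of 3 Raptor-knockout libraries, so the whole comparison is partly confounded with it. The labels number the Raptor-knockout animals 36, 47 and 54 and the double-knockout animals 74, 76, 78 and 81. Wild type has 38, 41, 73 and 77. Anything that goes with these animal numbers therefore cannot be told apart from genotype between the knockouts, and it was not tested. The insulin receptor adaptor Irs2 (ENSMUSG00000038894, chromosome 8, 10984681 to 11008458) stood at 58.9 ± 14.8 CPM in the double knockout and 17.9 ± 1.64 in the Raptor knockout, a rise of 3.29-fold (log2 fold change 1.72 ± 0.22, edgeR adjusted p = 0.00616). Wild type had 28.5 ± 5.20 CPM, so that Irs2 fell in the Raptor knockout and rose in the double knockout relative to it (edgeR adjusted p = 0.038 and 0.000667). The call of the rise against wild type ended in the libraries without Xist (0.67). Sdhd (ENSMUSG00000000171, chromosome 9, 50596357 to 50603812), a membrane anchor subunit of mitochondrial complex II, stood at 12.3 ± 3.39 CPM in the double knockout and 63.6 ± 22.4 in the Raptor knockout, 5.14-fold lower (log2 fold change -2.36 ± 0.34, edgeR adjusted p = 0.045). The third call, Gm43778, is an unconfirmed transcript annotated at chromosome 5, 55652949 to 55653147, and fell from 8.03 ± 1.42 to 0.486 ± 0.240 CPM (edgeR adjusted p = 0.0434). It falls outside the naming rule and was named after its values were seen.

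By edgeR 1 gene rose and 2 fell, with 997 at an unadjusted p under 0.05. The DESeq2 Wald test called 91 genes, 50 higher and 41 lower, with 853 at an unadjusted p under 0.05. The groups did not overlap for 12.2% of tested genes, where chance gives 5.71%. No gene was called without Raptor-knockout replicate 1 or 3, or with an Xist covariate. Without Raptor-knockout replicate 2 the counts were 9 and 18, with only the 2 groups in the fit 65 and 92, and without wild-type replicate 3 or 4, which enter through the shared dispersion, 28 and 97 genes in all. Sdhd lost its call without any Raptor-knockout or double-knockout library except Raptor-knockout replicate 2, as well as with library totals or a covariate for run or mt-Rnr2, while its log2 fold change stayed between -2.47 and -2.09. Irs2 lost its call without Raptor-knockout replicate 1 (1.80) or 3 (1.68), and on TPM, where both lost theirs, Irs2 was 1.43 or 1.70 and Sdhd -2.19 or -2.29 by the pseudocount. With an Xist covariate they were 1.35 and -2.53. Gm43778 lost its call without the same libraries as Sdhd, with a covariate for run, without the smaller run, on TPM and with an Xist covariate, where it was -2.88 against -3.94. Within the larger sequencing run, 2 genes rose and 0 fell, Irs2 among the calls and Sdhd not.

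Immediate early genes had a median log2 fold change of 0.92 in the double knockout relative to the Raptor knockout, with 0 of 20 members called (4 adjusted over the list alone). Jun stood at 154 ± 40.3 CPM against 71.02 ± 9.83 (log2 fold change 1.12, edgeR adjusted p = 0.307), was called by DESeq2 and with only the 2 groups in the fit, and was 0.31 with an Xist covariate and 0.53 in the libraries without Xist. Camera called the list (adjusted p = 3.33e-11), and the estimated correlation gave an adjusted p = 0.359. The groups differ in Xist as well, which was counted in 3 of 4 double-knockout and 0 of 3 Raptor-knockout libraries, and with an Xist covariate the median was 0.31 and the call ended. Ribosomal protein genes were a further 0.24 higher by their median, with 0 of 78 called (0 adjusted over the list alone; camera adjusted p = 1.14e-11, and adjusted p = 0.537 with an estimated correlation). Rpl23 stood at 1829 ± 78.6 CPM against 1489 ± 21.4. Developmental genes had a median of 0.29, with 0 of 16 called (5 adjusted over the list alone; camera adjusted p = 0.00134, and adjusted p = 0.282 with an estimated correlation). Desmin (Des), the intermediate filament of mature muscle, stood at 3682 ± 89.99 CPM against 3545 ± 183. Extracellular matrix genes had a median of 0.25, with 0 of 40 called (0 adjusted over the list alone; camera adjusted p = 0.00275, and adjusted p = 0.568 with an estimated correlation). The matrix median turned to -0.08 with an Xist covariate and -0.04 in the libraries without Xist, and its call ended without double-knockout replicate 1. Beside it, camera called fibro-adipogenic and fibroblast markers (median 0.17, camera adjusted p = 0.0281, and adjusted p = 0.592 with an estimated correlation) and macrophage and monocyte markers (median 0.16, camera adjusted p = 0.0281, and adjusted p = 0.568 with an estimated correlation), with 0 members called by edgeR. Both calls ended with an Xist covariate, in the libraries without Xist and without Raptor-knockout replicate 2 or double-knockout replicate 1 or 2, and the macrophage call also with no filter.

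Camera called the lists of fatty acid uptake and oxidation, the tricarboxylic acid cycle, nuclear-encoded oxidative phosphorylation and mitochondrially encoded genes lower in the double knockout than in the Raptor knockout, with an adjusted p from 0.382 to 0.774 with an estimated correlation. It did not call sterol and fatty acid synthesis (median 0.02, camera adjusted p = 0.579) or mitochondrial biogenesis regulators (-0.09, camera adjusted p = 0.493). Fatty acid genes had a median of -0.23, with 0 of 27 called (1 lower adjusted over the list alone; camera adjusted p = 0.00242, and adjusted p = 0.382 with an estimated correlation). Fabp3 stood at 101 ± 10.96 CPM against 189 ± 26.2 (edgeR adjusted p = 0.309) and was called with only the 2 groups in the fit. Tricarboxylic acid cycle genes had a median of -0.17, with 0 of 22 called (0 adjusted over the list alone; camera adjusted p = 0.00561, and adjusted p = 0.568 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes had a median of -0.08, with Sdhd the 1 gene called of 78 (1 adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.774 with an estimated correlation). Mitochondrially encoded genes had a median of -0.26, with 0 of 13 called (0 adjusted over the list alone; camera adjusted p = 0.0399, and adjusted p = 0.568 with an estimated correlation). This call ended with an Xist covariate, in the libraries without Xist, and without Raptor-knockout replicate 1 or 2 or double-knockout replicate 1 or 3. The developmental, fatty acid, cycle and oxidative phosphorylation calls each ended with an Xist covariate, and the oxidative phosphorylation median turned to 0.10. The fatty acid call also ended without the smaller run, and the cycle call in the libraries without Xist. The oxidative phosphorylation call also ended in those libraries, with a covariate for run or mt-Rnr2, without the smaller run, and without Raptor-knockout replicate 1 or double-knockout replicate 1 or 3.

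**Figure D5:**
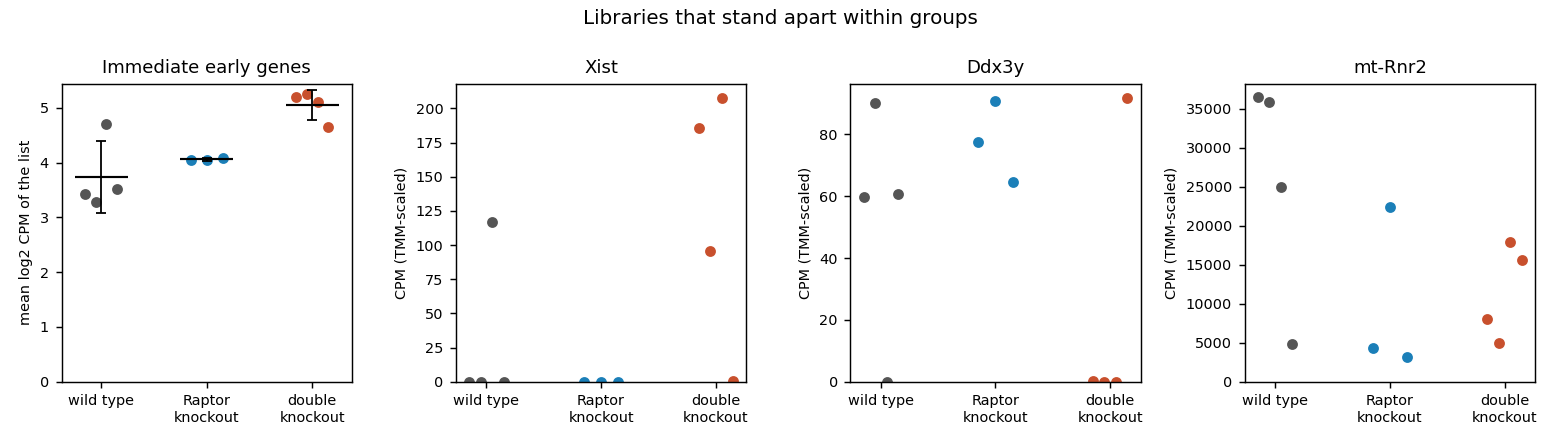
Mean log2 CPM of the immediate early gene list (with group mean and SD) and CPM (TMM-scaled) of Xist, Ddx3y and mt-Rnr2, with 1 point per library in each of the 3 genotypes and linear axes from 0. The immediate early gene mean of wild-type replicate 3 was 4.70 against 3.28 to 3.52 in the other wild-type libraries, and mt-Rnr2 ran from 3116 to 36524 CPM.

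Over the 40 lists, camera with the preset correlation called 19 in the double knockout against wild type, 16 in the Raptor knockout against wild type and 16 between the knockouts. With an estimated correlation 2, 1 and 0 held, and fry called 24, 20 and 0. The sign of the median, the mean or the test differed for 5, 7 and 5 lists.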

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

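Only the mt-Rnr2 covariate, and the setting of splits beside mt-Rnr2, were chosen after the results of this part were seen. Of 240 sets of 4 libraries, each the values of 1 named gene or library measure in 1 group, 12 held a library apart from the others beyond the 95% limit of Dixon's test, which is the 5% that chance gives. Wild-type replicate 3, the only wild-type library with Xist, held 4 of the 12. In that library Actr3b stood at 8.55 CPM against 33.6 to 36.7 in the other wild-type libraries, and Smox at 56.1 against 103 to 108. Rpl36a stood at 366 CPM there against 284 to 295, and Junb at 10.7 against 3.68 to 4.65. In wild-type replicate 4, Pvalb stood at 9332 CPM against 7600 to 7725 in the others and Tnnc2 at 24461 against 21652 to 22004. In wild-type replicate 1, Tpm1 stood at 21030 CPM against 19477 to 19687. In double-knockout replicate 2, Ttc9 stood at 29.6 CPM against 19.8 to 20.4 and Flrt1 at 12.4 against 26.9 to 29.4. Tnni1 stood at 77.6 CPM in double-knockout replicate 4 against 153 to 166, and Asb2 at 119.8 in double-knockout replicate 3 against 144 to 149. The total of double-knockout replicate 1 was 2.79 M counts (2791339) against 3.46 to 3.54 M in the others of its group.

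Other splits of the same libraries into groups of the same sizes were fitted in the same way. For the double knockout against wild type, 1 of 35 splits, the real one, called as many as 2802 genes. The highest other split called 23. This argues against chance, though 1 of 35 is the smallest share that these splits can give. For the Raptor knockout against wild type, 1 of 35 splits called as many as 1908 genes, and the highest other called 975. This argues against chance within the same limit. That other split differs from the real one by wild-type replicate 4, which it set with the knockouts, and points to a structure of the samples. It left wild-type replicates 1 to 3, with the highest mt-Rnr2 (24916 to 36524 CPM), against the remaining 4 (3116 to 22423 CPM), and the splits that set 1 other wild-type library with the knockouts called 0 to 81 genes. With an mt-Rnr2 covariate the real comparison called 870 genes higher and 1135 lower. For the double knockout against the Raptor knockout, 3 of 35 splits called 3 genes or more, so chance cannot be excluded. The highest other split there called 350 genes, which also points to a structure of the samples. It set Raptor-knockout replicate 2 with double-knockout replicates 1, 3 and 4, the 4 knockout libraries with the highest mt-Rnr2 (8087 to 22423 CPM), against the remaining 3 (3116 to 4967 CPM). With that covariate the real comparison called 7 genes higher and 8 lower.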

How the results depend on the processing

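The Xist covariate, the libraries without Xist alone and the mt-Rnr2 covariate were chosen after seeing the data. The cause was not tested for the changes given here, except where fewer libraries entered or where a scaling moved the median of all genes (by 0.23 and 0.20 with library totals, and 0.15 and 0.10 on TPM). Over all alternatives, log2 fold changes of named genes kept direction and side of the threshold in 3316 cases, lost the call in 126, gained one in 13 and changed sign in 14, and lists did so in 752, 71, 4 and 11. Most named genes were chosen for clear calls in these data, so these counts overstate how well calls hold. Over the alternatives planned beforehand, 63.2% (without the smaller run) to 99% (DESeq2 size factors) of all double-knockout calls against wild type held. For the Raptor knockout against wild type it was 58.4% (without Raptor-knockout replicate 1) to 97.7% (DESeq2 size factors). Lists were counted by the direction of the test and were not tested on TPM. The medians that turned with library totals or on TPM are therefore not among the 11. For the double knockout against wild type, library totals called 2421 genes higher and 844 lower. TPM called 779 lower with a pseudocount of 1 and 765 with 0.1, and the libraries without Xist (1 double-knockout library) called 238 and 234. For the Raptor knockout against wild type, library totals gave 1638 and 573, TPM 519 or 507 lower, and the libraries without Xist 555 higher. Between the knockouts, the counts higher and lower were 44 and 61 with no filter, 65 and 92 with only the 2 groups in the fit, 50 and 41 by DESeq2, and 7 and 8 with an mt-Rnr2 covariate. They were 2 and 0 with run as a covariate, 2 and 0 without the smaller run, 2 and 0 on TPM with a pseudocount of 0.1, and 0 and 0 with an Xist covariate or in the libraries without Xist. Library totals called 1 lower, and TPM with a pseudocount of 1 called 0 lower. Lists called between the knockouts fell from 16 to 1 with an Xist covariate and to 5 without the Xist libraries. With an estimated correlation 2, 0 and 1 lists were called (double knockout against wild type, between the knockouts, Raptor knockout against wild type), and fry called 0 between the knockouts.

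With each library left out in turn, the double knockout against wild type had 1009 (without double-knockout replicate 1) to 1655 (without wild-type replicate 4) genes higher, 1133 to 1689 lower and 16 to 22 lists. The Raptor knockout against wild type had 556 (without Raptor-knockout replicate 1) to 1203 (without wild-type replicate 4) higher, 584 to 1210 lower and 12 to 17 lists, with 597 and 627 without Raptor-knockout replicate 3. Between the knockouts there were 0 (without Raptor-knockout replicate 1 or 3) to 9 (without replicate 2) higher, 0 to 18 lower and 7 (without double-knockout replicate 1) to 21 lists. With the wild-type libraries split, the genes shared higher were 393, 405, 411, 418, 432 and 473, those shared lower 505, 542, 501, 536, 502 and 543, and r was 0.443, 0.591, 0.569, 0.578, 0.566 and 0.676, with fewer libraries in each fit.

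These values changed sign; none of the genes among them was called, and each of the lists except the autophagy list had a camera call with all libraries. Mtor in the Raptor knockout against wild type was 0.18 with library totals, and with libraries left out in turn it ran from -0.13 to 0.15 (without wild-type replicate 4), with 0.06 without Raptor-knockout replicate 1. Between the knockouts, Lpl was 0.0384 and Mef2c -0.11 with run as a covariate, and 0.038 and -0.11 without the smaller run. Rptor ran from -0.0326 (without Raptor-knockout replicate 1) to 0.16 with libraries left out in turn, and was -0.072 with an Xist covariate and -0.15 in the libraries without Xist. In these last 2 settings Mdh2 was 0.22 and 0.14, Nr4a1 -0.10 and -0.26, and the medians of the extracellular matrix list -0.0842 and -0.0357, fibro-adipogenic markers -0.0413 and -0.0045, adipocyte markers -0.0882 and -0.0576 and mitochondrially encoded genes, whose test turned in both, -0.0282 and 0.0193. Macrophage markers were -0.107 in the libraries without Xist. The oxidative phosphorylation list was 0.104 with an Xist covariate, and the autophagy list in the double knockout against wild type was 0.152 without the smaller run by its median, beside a test that gave a lower direction with all libraries. The covariate for sample-sheet number named the same libraries as the run covariate, and leaving out S1 and S2 the same as leaving out the smaller run. The larger run alone is the fit without the smaller run, and the smaller run holds double-knockout libraries only. No pairing was fitted, since the labels pair no animals. At this depth and spread, simulations with 200 changed genes per contrast recovered 10.6%, 6.25% and 1.52% of 1.5-fold changes.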

Other observations

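The genes in this paragraph and the comparison of Mtor TPM with its counts were chosen after their values were seen, as were the tests of endothelial and other cell markers, of terminal oligopyrimidine transcripts, of sex, of sequencing run and of internal A runs further on. The metallothioneins Mt1 and Mt2, which bind zinc and copper, rose in the double knockout against wild type (log2 fold changes 2.48 ± 0.53 and 2.73 ± 0.73, edgeR adjusted p = 0.00767 and 0.0253). Mt1 stood at 206.8 ± 93.4 CPM in the double knockout, 52.9 ± 5.01 in the Raptor knockout and 36.3 ± 24.9 in wild type. Myostatin (Mstn), a secreted inhibitor of muscle growth, fell in the double knockout (-1.19 ± 0.31, edgeR adjusted p = 0.0116) and was -0.98 ± 0.34 in the Raptor knockout (edgeR adjusted p = 0.0576). Its relative Gdf11 fell in both (-2.54 ± 0.31, edgeR adjusted p = 2.25e-05, and -1.64 ± 0.31, edgeR adjusted p = 0.00159). The muscle ubiquitin ligase Trim63, which rises in many forms of atrophy, fell in both knockouts (-1.04 ± 0.29, edgeR adjusted p = 0.0222, and -1.56 ± 0.33, edgeR adjusted p = 0.00698). Fbxo32, another such ligase, fell in the Raptor knockout (-1.09 ± 0.27, edgeR adjusted p = 0.0125) and was -0.62 ± 0.24 in the double knockout (edgeR adjusted p = 0.0729). In the libraries without Xist the double-knockout calls of Mt1 (2.40), Mt2 (2.75), Mstn (-1.32) and Trim63 (-0.63) and the Raptor-knockout call of Fbxo32 (-0.98) ended. The Mt2 call also ended with no filter, with only the 2 groups in the fit and without wild-type replicate 1 or double-knockout replicate 1 or 2, and without wild-type replicate 3 Mt2 was 3.53. The Mstn call in the double knockout ended with a run covariate, without the smaller run (-0.88) and on TPM, and a Raptor-knockout call was gained by DESeq2, with a run covariate and without wild-type replicate 4 (-1.24). The Trim63 call in the double knockout ended with library totals, with no filter, with a run or mt-Rnr2 covariate, without the smaller run, on TPM and without double-knockout replicate 1 or 3. The Fbxo32 call in the Raptor knockout ended on TPM, with an mt-Rnr2 covariate (-0.65) and without Raptor-knockout replicate 1 or 3, and a double-knockout call was gained by DESeq2 and without wild-type replicate 4 (-0.86).

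In the double knockout against wild type, nuclear-encoded oxidative phosphorylation genes had 3 higher and 13 lower of 78 (camera adjusted p = 0.201), and the sign of their median (-0.09) turned with library totals and on TPM, which moved the median of all genes by 0.23 and 0.15. Satellite cell markers had 2 of 10 higher (camera adjusted p = 0.0965), Schwann cell and nerve markers 3 of 10 (0.0786), and smooth muscle and pericyte markers 2 higher and 1 lower of 14 (0.665). Adipocyte markers had 1 of 16 higher with a median of 0.63 (camera adjusted p = 0.044, and adjusted p = 0.58 with an estimated correlation). That call ended with library totals, by DESeq2, with only the 2 groups in the fit, with an Xist or mt-Rnr2 covariate, in the libraries without Xist, and without wild-type replicate 1, 2 or 4 or double-knockout replicate 1 or 2. Erythroid markers had 1 of 9 lower (camera adjusted p = 0.649). Between the knockouts the adipocyte median was 0.78 (camera adjusted p = 0.0136, and adjusted p = 0.568 with an estimated correlation) and the erythroid median -0.93 (camera adjusted p = 0.0185, and adjusted p = 0.557 with an estimated correlation), with 0 genes of either list called by edgeR. Both calls ended with an Xist covariate, in the libraries without Xist and without Raptor-knockout replicate 2 or double-knockout replicate 2, and the erythroid call also without double-knockout replicate 1. Without Raptor-knockout replicate 2 the erythroid median was -0.16, and without double-knockout replicate 2 the adipocyte median was 0.45 and, against wild type, 0.29.

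The deposited TPM of Mtor stood apart from its counts. TPM per CPM (here unscaled, per library total) of Mtor was 0.797 to 0.925 in the 4 double-knockout libraries and 0.123 to 0.21 in the other 7. Its TPM was 26.8 to 38.7 in the double knockout and 1.97 to 4.98 elsewhere. Among 9354 genes with at least 5 counts in every library, Mtor ranked 1 by the rise of this ratio in the double knockout (log2 2.46). Rptor had 0.265, the median over these genes was -0.035 and their 97.5th percentile 0.204. The annotation holds 4 Mtor transcripts of 8564, 1003, 2229 and 598 bases. Those of 1003 and 2229 bases end at 148454973 and 148454969, in the first part of the gene. A higher TPM per CPM follows from a shorter length given to the gene by the authors' tool. More Mtor counts assigned to shorter transcripts in the double knockout would give it. The rise of the counts therefore need not come from the transcript of 8564 bases. Which transcript the counts came from was not tested.

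Ribosomal protein transcripts were higher in both knockouts, with medians of 0.93 in the double and 0.69 in the Raptor knockout. Lists matched on expression, transcript length and GC content argue against those as the cause within the range matched (middle of 10000 lists -0.0238 and 0.0218, highest 0.243 and 0.256). The match was not exact. The ribosomal genes had medians of 8.99 log2 CPM and 1076.5 bases, and the matched genes 8.29 and 1219. Lengths were those of the longest annotated transcript of each gene. The summed CPM of ribosomal genes and 168 processed pseudogenes also rose (log2 0.88 and 0.65), which argues against reads moved from pseudogenes. A lower share of myofibre RNA would raise markers of all other cells alike only if those cells were otherwise unchanged, which was not tested. Endothelial markers (medians 0.11 and 0.15, upper quartiles 0.27 and 0.26) stayed below the lower quartiles of the ribosomal genes (0.75 and 0.54) and of macrophage markers (0.68 and 0.48). Macrophage (medians 0.98 and 0.76), fibro-adipogenic (0.60 and 0.41) and tenocyte markers (0.81 and 0.69) were higher with the ribosomal list, so more RNA from those cells stays open. A candidate explanation is a rise of transcripts with a 5' terminal oligopyrimidine tract as a class, since 18 non-ribosomal members, 11 of them in the fixed lists, had medians of 0.64 and 0.56, reached by 0 of 10000 lists matched on expression, a hypothesis found and tested on the same data.

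Immediate early genes had a median of 0.92 in the double knockout relative to the Raptor knockout. Without the smaller run it was 1.05 (camera adjusted p = 3.46e-11), which argues against sequencing run as the cause. With an Xist covariate it was 0.31 (camera adjusted p = 0.0933). In the libraries without Xist it was 0.54, with 1 double-knockout library and the spread taken from the other groups. Sex and genotype cannot be told apart for this list, because Xist was counted in 3 of 4 double-knockout and in 0 of 3 Raptor-knockout libraries. The list mean was 4.64 log2 CPM in double-knockout replicate 4, which lacks Xist, 5.10 to 5.26 in the other double-knockout libraries and 4.04 to 4.09 in the Raptor knockout.

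The 16S mitochondrial ribosomal RNA mt-Rnr2 ranged 3.55 on the log2 scale between libraries, 2.92 within wild type and 2.85 within the Raptor knockout, all of them in the larger run, and 1.85 within the double knockout. A candidate explanation is priming at internal A runs. Over 10482 genes, which are not independent, an A run of 10 bases more than 200 bases from the transcript end raised the odds of varying in the same direction as mt-Rnr2 within groups 1.77-fold (95% interval 1.58 to 1.99), with length (1.31 per doubling) and GC content (0.893 per percent) in the model. No biological explanation was tested, and RNA quality, for which the labels give no values, stays open.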
